A study of Mus musculus with 15 samples.

How the data were processed

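Poly(A) RNA from E14 mouse embryonic stem cells was sequenced in 15 libraries, 3 biological replicates in each of 5 groups (EGFPKD, Ddx10KD, Ddx24KD, Ddx27KD and Ddx54KD). Per the labels, cells on 0.2% gelatin were incubated for 16 h with 400 ng of small interfering RNA and 4 µL of Lipofectamine and harvested at 48 h, and libraries were made after oligo-dT capture. For each library the authors deposited gene values from RSEM on mm10, per the submitters' processing notes. The RSEM version, aligner and annotation release are not given in the sources used here. Per the file headers these values are expected counts, which are estimated reads per gene with no scaling for depth, TPM (transcript abundances scaled to the same sum in each library), FPKM (fragments per kilobase, scaled for depth) and transcript lengths. The authors also deposited 1 EBSeq table for each knockdown. In these tables the deposited posterior probabilities of equal and of differential expression are scores per gene that sum to 1, and the deposited fold changes are ratios of the knockdown to the control. Their settings are not given.

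Libraries held 26836946 to 27708782 expected counts, with at least 1 count in 16861 to 17176 genes, and the 10 most abundant genes held 5.24% to 6.03% of the counts. Expected counts were rounded to integers, genes were filtered with filterByExpr (14335 of 23845 kept, about 99.97% of the counts), and libraries were scaled by TMM. Groups were compared with the edgeR quasi-likelihood test in 1 fit of the 15 libraries, and p values were adjusted over all tested genes by the Benjamini-Hochberg method. Genes at an adjusted p under 0.05 are called. The comparisons were the 4 knockdowns against EGFPKD, the 6 pairs of knockdowns and a test over all 5 groups. Levels are TMM-scaled CPM (counts scaled to library size), given as mean and SD over 3 libraries, and log2 changes are fitted values with their SE. The counting intervals of ratios for genes with few counts are exact binomial intervals at 95% on summed expected counts and cover counting error only. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

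Replicate numbers were checked for pairing. After group means were removed, all 30 correlations between libraries of the same number in different groups were above 0.1 (0.106 to 0.335), and each of the 15 libraries resembled those of its own number most. The numbers therefore pair the libraries, and every edgeR and list test of the 15 libraries was repeated with the replicate number as a block. Fits with libraries left out, or of the compared groups alone, ignored this pairing, so calls lost in them were lost in unpaired fits. Blocked values stand beside a list test where they change its call, beside the count of genes of a comparison where they move it by more than 1.5 times, and beside the called members given for a list where they move either direction by more than 1.5 times and at least 2 genes. Replicates of a group differed by more than counting noise, with a mean chi-squared per gene of 5.80 to 20.7.

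Before the data were examined, 25 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The lists were the 4 targets, other DEAD-box genes, p53 targets, pluripotency, endoderm, mesoderm, ectoderm, trophoblast, 2-cell-like genes, ribosome assembly, RNA polymerase I, ribosomal proteins, snoRNA hosts, R-loop factors, ATF4 targets, HSF1 chaperones, endoplasmic reticulum stress, interferon, G2 and mitosis, S phase, cholesterol, glycolysis and hypoxia, fibroblast markers, histones and mitochondrial messages. Of these 23 were tested as lists, the targets singly, and the mitochondrial genes were absent from the files. Named genes are the targets and, against EGFPKD, up to 8 genes each way with the largest log2 change among called genes with a mean TPM of at least 5 in a group and no overlap between the 3 knockdown and 3 control values. Further named genes are up to 4 members with the smallest p of each list that is called or has at least 3 called members, up to 3 genes each way between knockdowns, 10 genes changed alike in all 4 knockdowns, and Pou5f1, Nanog, Sox2, Cdkn1a and Mdm2. Predicted gene models were counted but not named, apart from list members. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with the directional test fry, all on the edgeR counts and dispersions. In these tests camera compares a list with all other genes, and fry tests whether a list's genes move, on balance, one way, and compares them with nothing else. Adjusted p of list tests cover the 23 lists of a comparison.

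The alternatives were RLE and upper-quartile factors, DESeq2, limma-voom, no count filter, a filter of 10 CPM in at least 3 libraries, the replicate block, fits of the compared groups alone, each library left out in turn, a 2-fold minimum, an adjusted p under 0.01, a posterior probability of 0.99, and other list tests. Added after the data were seen were the block together with a correction of each library for gene length and GC content (a first version also removed each library's mean, and was revised after its result was seen to remove the trend alone), and a fit without the replicate 2 libraries of all 5 groups, since Ddx24KD replicate 2 stood apart. Shared controls were examined with 20 simulated sets of unchanged groups, in which the control libraries were redrawn too. For tests on simulated data, counts were drawn from the EGFPKD means, and genes were changed in the libraries of Ddx10KD. The fit recovered 36% of genes changed 1.25-fold, 74% at 1.5-fold, 88% at 2-fold and 96% at 4-fold (50 genes each). Of the calls, 4.55% were unchanged genes. In simulated lists, camera called 1 of 1 raised list and 0 of 5 unchanged lists. Simulated genes were drawn independently, so these lists could not show false calls that come from correlation between genes. Gene positions are from GENCODE M21 on GRCm38, which is mm10, matched by symbol for 13740 of the 14335 tested genes (95.8%).

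The deposited ratios were recomputed from the deposited expected counts, as ratios of group means after median-of-ratios scaling with 0.01 added to each mean, for 12896 genes with a mean of at least 20 counts. For Ddx10KD, Ddx27KD and Ddx54KD, all 12896 ratios came out within 1e-06 on the log2 scale. For Ddx24KD 1 did, with a median difference of 0.0363 and a largest of 1.08 (log2). That table lists 18662 genes where the 6 libraries detect 18680, with 113 listed but not detected and 131 detected but not listed. Leaving out EGFPKD replicate 2 brought the genes detected but not listed to 0, and leaving out any 1 of the other 5 libraries kept them at 131. No other deposited library put in its place gave the ratios (smallest median difference 0.0612).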

Results

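The data were 15 poly(A) RNA sequencing libraries from E14 cells, a line of mouse embryonic stem cells. Cells had received small interfering RNA against EGFP (EGFPKD, the control) or against 1 of 4 DEAD-box RNA helicases (Ddx10KD, Ddx24KD, Ddx27KD and Ddx54KD), with 3 biological replicates in each of the 5 groups. By its title, the series concerns proteins that bind R-loops, which are hybrids of RNA and DNA, and their part in the processing of ribosomal RNA. Each library held 26836946 to 27708782 expected counts, and 14335 of 23845 genes passed the count filter. The first principal component of log CPM (counts scaled to library size) held 42.0% of the variance. EGFPKD libraries lay between -45.2 and -39.7 on it, and knockdown libraries between -2.67 and 20.1. Replicate 2 of Ddx24KD stood apart on the component that held 5.07% of the variance, at -23.2, where the other 14 libraries lay between -5.72 and 10.1.

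All 4 targeted transcripts fell in their own knockdown. Ddx10 was at 18.5% ± 4.25 of its EGFPKD level (SD, n = 3) in Ddx10KD, and Ddx24 at 30.8% ± 4.89 in Ddx24KD. Ddx27 was at 22.7% ± 0.818 in Ddx27KD, and Ddx54 at 28.0% ± 4.68 in Ddx54KD. The fitted log2 changes were -2.43 ± 0.11 (SE), -1.70 ± 0.08, -2.14 ± 0.06 and -1.84 ± 0.08, with edgeR adjusted p of 1.77e-09, 7.09e-09, 7.61e-13 and 2.90e-09. The control levels were 146 ± 4.75 CPM for Ddx10, 177 ± 6.45 for Ddx24, 202 ± 2.76 for Ddx27 and 204 ± 1.74 for Ddx54 (SD, n = 3). In GENCODE M21 on mm10, Ddx10 lies on chromosome 9, 53098635 to 53248053, reverse strand, ENSMUSG00000053289.8, and Ddx24 on chromosome 12, 103407982 to 103425830, reverse strand, ENSMUSG00000041645.14. Ddx27 lies on chromosome 2, 167015193 to 167034947, forward strand, ENSMUSG00000017999.16, and Ddx54 on chromosome 5, 120612739 to 120628592, forward strand, ENSMUSG00000029599.13.

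Smaller changes appeared among the targets in the other knockdowns. Ddx24 was at 79.1% ± 0.267 of control in Ddx10KD (adjusted p 0.00412), and Ddx27 was at 85.3% ± 4.24 in Ddx54KD (adjusted p 0.00624). Ddx24 was also called in Ddx27KD, at 84.8% ± 2.24 with adjusted p 0.0289. In fits that ignore the pairing, that call was lost without EGFPKD replicate 1 (0.1002) or 2 (0.0547) and without Ddx27KD replicate 1 (0.0564), 2 (0.0522) or 3 (0.0883). With all libraries and the block its adjusted p was 0.00259. With the replicate number as a block, calls were added for Ddx24 in Ddx54KD, Ddx27 in Ddx24KD and Ddx54 in Ddx27KD. There the adjusted p went from 0.0657 to 0.00833, from 0.170 to 0.0252 and from 0.151 to 0.0430. The remaining 6 of these 12 values were not called, and lay between 87.5% and 100.3% of control.

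**Figure D1:**
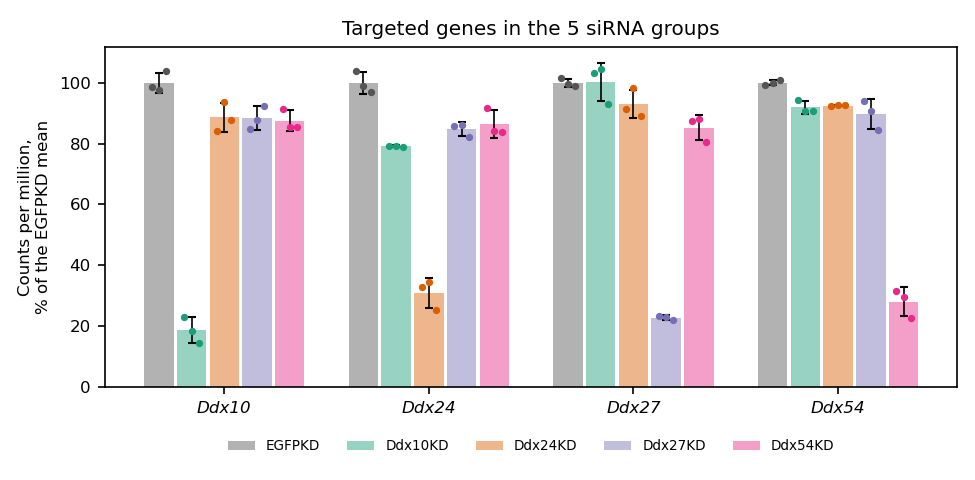
Level of each targeted transcript as a percentage of its EGFPKD mean, in the 5 groups. Bars are means, error bars are SD, dots are the 3 libraries of a group. Each gene was lowest in its own knockdown, between 18.5% and 30.8% of control.

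The comparison of Ddx10KD with EGFPKD asked which transcripts changed when Ddx10 was depleted. Genes under p53 rose: 28 of 31 tested p53 targets were called higher (28 adjusted over the list alone), with a median log2 change of 1.06. Plk2, a polo-like kinase, went from 21.6 ± 2.97 to 126 ± 17.2 CPM (SD, n = 3), and the BH3-only gene Pmaip1 from 12.3 ± 0.813 to 39.7 ± 3.77 CPM. The cyclin-dependent kinase inhibitor Cdkn1a rose by 1.43 ± 0.16 (log2, SE), Mdm2, which degrades p53, by 1.64 ± 0.16, Phlda3 by 1.77 ± 0.12 and Ddit4l by 2.44 ± 0.19. Largest changes, here and for the other knockdowns, are among genes that pass the naming rule (mean TPM of at least 5 in a group, no overlap of the replicates). Outside the p53 list, the largest increases of this kind were in the anoctamin Ano3 (3.46), carboxypeptidase Z (Cpz, 3.32), Ms4a10 (from 0.958 ± 0.187 to 8.87 ± 1.31 CPM), the protease inhibitor Serpine2 (3.17), the Wnt ligands Wnt8a (3.07) and Wnt5a (2.98), Cd109 (2.83) and the neurogenic factor Neurod1 (2.68).

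Of 33 targets of ATF4, the transcription factor of the integrated stress response, 24 fell and 2 rose in Ddx10KD (25 and 2 adjusted over the list alone). Among them were the mitochondrial folate enzyme Mthfd2 (-0.86 ± 0.06, log2, SE), the transfer RNA synthetases Nars (-0.80 ± 0.07) and Aars (-0.80 ± 0.08), and the serine synthesis enzyme Psat1 (-0.94 ± 0.09). The largest decreases apart from Ddx10 were in the stress gene Nupr1 (-2.44), the glutathione-degrading enzyme Chac1 (-2.09), Rpl22l1 (-1.57), Hopx (-1.47), Fgf17 (-1.46), Pck2 (-1.43) and Cd74 (-1.41). S-phase genes fell in 24 of 32 cases (24 over the list alone), among them Uhrf1 (-0.53), the replication clamp Pcna (-0.52) and the helicase subunit Mcm6 (-0.37). Cholesterol genes fell in 17 of 25 cases (18 over the list alone), with Ebp at -0.43 and Fdps at -0.40. Glycolysis and hypoxia genes fell in 15 of 27 cases and rose in 2 (16 and 2 over the list alone), with the enzymes Tpi1 at -0.65 and Pgam1 at -0.34 and the glucose transporter Slc2a1 higher at 0.30.

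Pluripotency genes were lower in part: 13 of 26 fell (14 over the list alone; 16 lower and 2 higher with the block), including Tcl1 (-0.60), Zfp42 (-0.33), Trim28 (-0.34) and Nanog (-0.47). Pou5f1 (-0.10 ± 0.05, adjusted p 0.144) and Sox2 (0.12 ± 0.05, 0.0934) were not called, though both were with the replicate block. Mesoderm markers rose in 6 of 16 cases (6 over the list alone; 7 higher and 2 lower with the block), with Nodal at 0.83, Mesp2 at 1.19 and Lefty1 at 0.85. In all, edgeR called 4438 of 14335 genes, 2363 higher and 2075 lower, of which 713 changed at least 2-fold. The directional test fry called 10 of 23 lists, with adjusted p of 1.26e-05 for p53 targets, 1.20e-04 for ATF4 targets, 1.66e-04 for S-phase genes, 0.0224 for cholesterol, 0.0469 for glycolysis, 1.66e-04 for pluripotency and 3.42e-05 for mesoderm. Against all other genes, camera with an estimated correlation called p53 targets alone (adjusted p = 0.0326), and that call was lost with the replicate block (0.101). The others had adjusted p = 0.135 (ATF4), 0.219 (S phase), 0.740 (cholesterol), 0.740 (glycolysis), 0.135 (pluripotency) and 0.135 (mesoderm) with an estimated correlation.

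Ddx24KD, compared with EGFPKD to find the transcripts that changed when Ddx24 was depleted, had higher levels of genes of the 2-cell-embryo-like state. Of 24 tested members 18 rose and 1 fell (19 and 1 adjusted over the list alone), and the median log2 change was 0.91. The cluster gene Zscan4f rose by 0.94 ± 0.17 (log2, SE), Zscan4b by 1.13 ± 0.22, AF067061 by 1.02 ± 0.18 and Gm8300 by 0.81 ± 0.15. In the authors' deposited table their log2 ratios were 0.69, 0.68, 0.96 and 0.66, in that order. There AF067061 alone passed a probability of 0.95, against 0.859 for Zscan4f, 0.230 for Zscan4b and 3.66e-06 for Gm8300. The ratios of that table did not follow from the deposited libraries. Per library, the list's median log2 level against the EGFPKD mean was -0.057, -0.23 and 0.28 in EGFPKD replicates 1 to 3. It was 0.73 to 0.92 in Ddx24KD. The 5 Zscan4 genes summed to 96.3 ± 19.4 CPM in Ddx24KD and 49.8 ± 8.11 in EGFPKD (SD, n = 3), and the whole list to 197 ± 28.8 and 158 ± 13.0 CPM. Tests on this list gave adjusted p 0.00132 by fry, and adjusted p = 0.309 with an estimated correlation.

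Genes under p53 rose here too, 27 of 31 (27 higher and 1 lower over the list alone), with a median of 1.06. Plk2 went from 21.6 ± 2.97 to 124 ± 28.0 CPM (SD, n = 3), and the antiproliferative gene Btg2 rose by 1.93 ± 0.15 (SE), Mdm2 by 1.73 ± 0.16 and Cdkn1a from 31.3 ± 1.73 to 72.0 ± 23.0 CPM. Ano3 (3.50), Cpz (3.37), Serpine2 (3.03), Wnt5a (3.01), Ms4a10 (2.97), the receptor-type phosphatase Ptprv (2.81) and Neurod1 (2.59) were among the largest increases. Of the ectoderm list, 4 of 14 rose and 2 fell (6 and 3 over the list alone, 7 and 4 with the block). The list had adjusted p 0.0268 by fry, and adjusted p = 0.722 with an estimated correlation. Its members Otx2 (1.49 ± 0.18), Pou3f1 (1.51 ± 0.24) and Fgf5 (1.38 ± 0.30) were higher. By the authors' deposited log2 ratios, Otx2 and Pou3f1 were also higher in Ddx10KD (1.45 and 1.52) and in Ddx27KD (1.33 and 1.33). Mesoderm markers rose in 7 of 16 cases (7 over the list alone), with Nodal at 0.86 and Wnt3 at 2.29.

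ATF4 targets fell in 24 of 33 cases and rose in 2 (24 and 2 over the list alone), with Mthfd2 at -0.77 ± 0.06, Nars at -0.67 ± 0.07 and Psat1 at -0.79 ± 0.09 (log2, SE). Besides Ddx24, the largest decreases were in Nupr1 (-1.89), the glutathione-cleaving enzyme Ggt1 (-1.55), Chac1 (-1.45), the activin subunit Inhbb (-1.45), the protease Napsa (-1.36), Hopx (-1.29) and Fgf17 (-1.29). S-phase genes fell in 21 of 32 cases (24 over the list alone; Uhrf1 -0.48, Cdt1 -0.33), cholesterol genes in 14 of 25 (15; Ebp -0.56), and pluripotency genes in 10 of 26, with 1 higher (11 and 1, or 13 and 3 with the block; Tcl1 -0.57, Klf2 -0.37). Mitotic genes rose in 11 of 25 cases (12 higher and 1 lower over the list alone, 14 and 3 with the block), by small amounts such as 0.26 for the kinesin Cenpe and 0.23 for Prc1. Nanog fell by 0.32 on the log2 scale, Sox2 rose by 0.24, and Pou5f1 was at -0.11 (adjusted p 0.111, called with the replicate block).

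By edgeR, 4026 genes were called in Ddx24KD, 2154 higher and 1872 lower, and 646 changed at least 2-fold. By fry 10 of 23 lists were called, with adjusted p of 3.26e-05 for p53 targets, 3.86e-05 for mesoderm, 2.80e-04 for ATF4 targets, 4.60e-04 for S phase, 0.00132 for pluripotency, 0.00736 for mitosis and 0.0160 for cholesterol. With an estimated correlation, camera kept p53 targets (adjusted p = 0.0354, or 0.0727 with the block). It gave adjusted p = 0.151 (mesoderm), 0.152 (ATF4), 0.263 (S phase), 0.263 (pluripotency), 0.722 (mitosis) and 0.666 (cholesterol) with an estimated correlation.

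Ddx27KD was compared with EGFPKD in the same way, for depletion of Ddx27. Plk2 went from 21.6 ± 2.97 to 160.3 ± 12.5 CPM (SD, n = 3), Mdm2 rose by 1.99 ± 0.16 (log2, SE), Cdkn1a by 1.56 ± 0.16, Btg2 by 2.21 ± 0.15 and Phlda3 by 1.86 ± 0.12. They belong to the p53 targets, of which 28 of 31 rose and 1 fell (29 and 1 over the list alone), with a median of 1.28. Among the largest increases were Cpz (3.58), Ano3 (3.55), Ms4a10 (3.36), Serpine2 (3.18), Ptprv (3.06), Wnt5a (2.98) and the leukotriene receptor Ltb4r2 (2.92). Mesoderm markers rose in 7 of 16 cases and fell in 1 (7 and 1 over the list alone), among them the Nodal pathway genes Nodal (1.05) and Lefty1 (1.13).

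Factors of ribosome assembly were lower in Ddx27KD, where 32 of 86 fell and 5 rose (33 and 6 over the list alone, 50 and 8 with the block), all by modest amounts. Nop10, of the pseudouridylation complex, was at -0.45 ± 0.06 (log2, SE), Pno1 at -0.32 ± 0.05 and Rrp1 at -0.24 ± 0.04, while Utp20 was higher at 0.42 ± 0.05. ATF4 targets fell in 23 of 33 cases and rose in 2 (24 and 2 over the list alone), with the serine synthesis enzyme Phgdh at -1.10 ± 0.11 and Mthfd2 at -0.98 ± 0.06. The largest decreases after Nupr1 (-2.25) and Ddx27 were in Chac1 (-1.83), Fgf17 (-1.65), the germ cell gene Stra8 (-1.50), Rpl22l1 (-1.45), Ggt1 (-1.37) and Inhbb (-1.36). S-phase genes fell in 21 of 32 cases (23 over the list alone; Pcna -0.54, Cdt1 -0.38), and cholesterol genes in 16 of 25 (19; Sqle -0.47, Cyp51 -0.50). Pluripotency genes fell in 12 of 26 cases and rose in 1 (12 and 1, or 15 and 3 with the block; Zfp42 -0.40, Nr0b1 -0.54, Nanog -0.43). Sox2 rose by 0.26. Pou5f1 was called at -0.18 (adjusted p 0.0133), but not without EGFPKD replicate 2 (0.0505) or Ddx27KD replicate 3 (0.0646).

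This knockdown had 4788 called genes by edgeR, 2480 higher and 2308 lower, with 796 changed at least 2-fold. The 10 lists called by fry included p53 targets (adjusted p 3.34e-06), mesoderm (4.46e-06), ATF4 targets (1.87e-04), S phase (1.87e-04), pluripotency (2.17e-04), cholesterol (0.00562) and ribosome assembly (0.0216). With an estimated correlation, p53 targets had adjusted p = 0.0189. The other 6, in that order, had adjusted p = 0.127, 0.182, 0.259, 0.182, 0.641 and 0.826 with an estimated correlation. With the replicate block the estimate for mesoderm was 0.0473.

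Ddx54KD, compared with EGFPKD for depletion of Ddx54, had the fewest genes called by edgeR of the 4 knockdowns, in the fit of all 15 libraries. In the authors' deposited tables the fewest, at a probability of at least 0.95, were for Ddx24KD, 2316 against 2445 for Ddx54KD. The deposited Ddx24KD ratios did not follow from the deposited libraries, while those of Ddx54KD did, so these counts may not be comparable. Again 28 of 31 p53 targets rose in Ddx54KD (28 over the list alone), with a median of 0.95. Plk2 went from 21.6 ± 2.97 to 116 ± 9.89 CPM (SD, n = 3), and Btg2 (1.92 ± 0.15, log2, SE), Ddit4l (2.35 ± 0.19), Mdm2 (1.60 ± 0.16) and Cdkn1a (1.26 ± 0.16) rose. Cpz (3.41), Ano3 (3.15), Ms4a10 (3.02), Ptprv (2.73), Serpine2 (2.64) and the annexin Anxa8 (2.44) were, with Plk2, among the largest increases. Genes of the 2-cell-like state rose in 11 of 24 cases (14 over the list alone), with a median of 0.55, and among them were Usp17le (1.09 ± 0.25), Tcstv3 (0.91 ± 0.19) and Zscan4f (0.66 ± 0.17). Mesoderm markers rose in 6 of 16 cases (6 over the list alone; Wnt3 2.47, Nodal 0.73).

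ATF4 targets fell in 24 of 33 cases and rose in 2 (24 and 2 over the list alone), with the proline synthesis enzyme Aldh18a1 at -0.83 ± 0.09 and Mthfd2 at -0.88 ± 0.06 (log2, SE). Nupr1 (-1.89), Chac1 (-1.58), Fgf17 (-1.37), Hopx (-1.26), Gdf1 (-1.24), Apol6 (-1.23) and Ggt1 (-1.19) had the largest decreases besides Ddx54. Ribosome assembly factors fell in 26 of 86 cases and rose in 2 (29 and 3 over the list alone, 45 and 6 with the block; Nop10 -0.42, Noc4l -0.33). S-phase genes fell in 21 of 32 (25; Uhrf1 -0.48, Pcna -0.45), cholesterol genes in 12 of 25 (15; Ebp -0.49, Cyp51 -0.55), and pluripotency genes in 9 of 26, with 1 higher (11 and 1, or 12 and 5 with the block; Jarid2 -0.30, Tcl1 -0.47). Sox2 rose by 0.23, and Nanog was at -0.19 (adjusted p 0.0730, called with the replicate block). Pou5f1 was called at -0.16 (adjusted p 0.0337). That call was lost without EGFPKD replicate 2 (0.0993) or 3 (0.0868), without Ddx54KD replicate 1 (0.0628) or 3 (0.164), and in a fit of the compared groups alone (0.0601).

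In Ddx54KD, edgeR called 3483 genes, 1878 higher and 1605 lower, and 534 changed at least 2-fold. With the replicate block 5570 were called, without Ddx54KD replicate 3 the count was 2232, and without all replicate 2 libraries, a choice made after the data were seen, it was 2161. Adjusted p by fry were 2.07e-05 (p53), 7.62e-05 (mesoderm), 1.68e-04 (ATF4), 3.40e-04 (S phase), 0.00303 (pluripotency), 0.0161 (cholesterol), 0.0173 (2-cell-like) and 0.0249 (ribosome assembly), among 10 lists called. With an estimated correlation p53 targets had adjusted p = 0.0228 (0.104 with the block). The other 7, in that order, had adjusted p = 0.172, 0.121, 0.223, 0.254, 0.610, 0.713 and 0.713 with an estimated correlation.

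**Figure D2:**
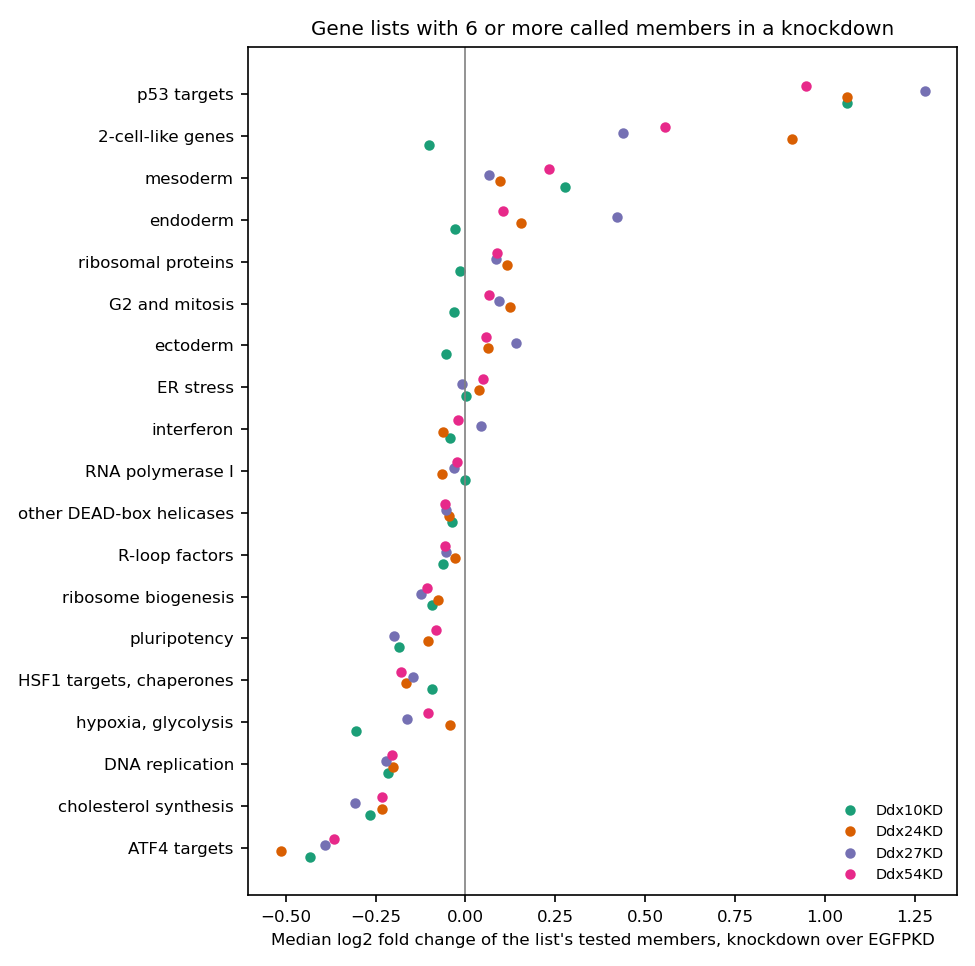
Median log2 change of the tested members of each gene list in the 4 knockdowns against EGFPKD, for lists with at least 6 called members in a knockdown. Medians of p53 targets lay between 0.95 and 1.28 in all 4, and those of 2-cell-like genes between -0.10 in Ddx10KD and 0.91 in Ddx24KD.

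Other lists gave smaller or mixed changes against EGFPKD. In Ddx10KD and Ddx24KD, 25 and 22 of 86 ribosome assembly factors fell and 3 rose in each (the same counts over the list alone; 34 and 36 lower and 10 and 8 higher with the block), with fry adjusted p 0.0695 and 0.0700 (0.00289 and 0.00259 with the block) and adjusted p = 0.812 and 0.722 with an estimated correlation. Ribosomal protein genes rose in 14 of 79 cases and fell in 1 in Ddx24KD (6 and 1 over the list alone, 46 and 1 with the block), with Rpl23a at 0.23 and Rps3 at 0.20 and Rpl3 lower at -0.22. Called counts were 3 higher and 8 lower in Ddx10KD, 8 and 2 in Ddx27KD, and 6 and 1 in Ddx54KD, and with the block 7 and 14, 34 and 2, and 35 and 1. Their fry adjusted p ran from 0.0998 to 0.788. With the block it was 0.470 in Ddx10KD, 0.00259 in Ddx24KD, 0.0144 in Ddx27KD and 0.0158 in Ddx54KD. They had adjusted p = 0.798 to 0.930 with an estimated correlation, and 0.502 to 0.889 with the block. Factors that limit R-loops went both ways: 3 or 4 of 37 rose and 6 fell in each knockdown, and 5 to 9 rose and 9 to 12 fell with the block. The THO subunit Thoc6 rose by 0.62 to 0.75 and the topoisomerase Top3b by 0.51 to 0.72, and Brca1 was at -0.30 in Ddx24KD and -0.31 in Ddx27KD. Of 16 RNA polymerase I genes, 1 or 2 rose and 2 to 4 fell, with the nucleolar factor Tcof1 at -0.33 to -0.20. Of 31 other DEAD-box genes, 2 or 3 rose and 4 or 5 fell (3 to 6 and 7 to 10 with the block), with Ddx59 at 0.39 to 0.59 and the junction complex helicase Eif4a3 at -0.27 to -0.23. By fry these 3 lists had adjusted p of 0.108 to 0.401, 0.242 to 0.352 and 0.106 to 0.288. With the block, R-loop factors had 0.135 to 0.578, while the RNA polymerase I list was called in Ddx10KD (0.0183), Ddx27KD (0.0253) and Ddx54KD (0.0285) and not in Ddx24KD (0.0616). The DEAD-box list was called with the block in Ddx10KD (0.0183) and Ddx54KD (0.0285), and not in Ddx24KD (0.0787) or Ddx27KD (0.0518). With an estimated correlation and the block, these 2 lists had adjusted p = 0.679 to 0.767.

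The RNA sensor genes Oas1a and Ddx58 were lower in all 4 knockdowns. Oas1a was at -0.89 to -0.52 and Ddx58 at -0.75 to -0.55 (log2), in an interferon list of which 3 to 6 of 17 members fell (3 to 6 over the list alone, 6 with the block; fry adjusted p 0.0469 to 0.219, and 0.00263 to 0.0285 with the block, or 0.433 to 0.680 with the block and an estimated correlation). HSF1 targets and chaperones fell in 6 or 7 of 17 cases and rose in 1 to 3, with the co-chaperones Ahsa1 at -0.37 to -0.29 and Stip1 at -0.26 to -0.18 and fry adjusted p 0.0243 to 0.0966. With the block 9 or 10 fell and 2 or 3 rose, and the list was called in all 4 (at most 5.00e-04, or 0.292 to 0.433 with an estimated correlation). Of 18 genes of endoplasmic reticulum stress, 3 or 4 rose and 1 to 5 fell (fry 0.1198 to 0.652; with the block 4 to 7 rose, 2 to 8 fell and Ddx24KD was called, at 0.0322, or 0.782 with an estimated correlation), with Herpud1 at -1.14 to -0.71. Endoderm markers went both ways, 2 to 4 of 17 higher and 3 to 5 lower (3 to 5 and 4 to 6 with the block; fry 0.544 to 0.978), with Cxcr4 at 1.05 to 1.43, Hnf4a at 1.53 to 1.77 and the laminin gene Lama1 at -0.49 to -0.36. Ectoderm markers rose in 5, 3 and 1 of 14 cases and fell in 5, 4 and 4 in Ddx10KD, Ddx27KD and Ddx54KD (fry 0.253 to 0.485). With the block 5, 5 and 3 rose and 5, 5 and 6 fell, with fry adjusted p 0.00289, 0.00499 and 0.297, and with an estimated correlation 0.609, 0.680 and 0.748. Trophoblast markers rose in 1 or 2 of 13 cases and fell in up to 2 (fry 0.446 to 0.980), or 2 or 3 and 1 to 3 with the block, which called Ddx54KD (0.0429, or 0.708 with an estimated correlation). In Ddx10KD, Ddx27KD and Ddx54KD, 1 to 7 of 25 mitotic genes rose and 2 or 3 fell (fry 0.0318 to 0.311). With the block 3, 11 and 9 rose and 9, 2 and 4 fell (fry 0.0496, 0.00194 and 0.0285; with an estimated correlation 0.792, 0.767 and 0.796). In Ddx24KD, Ddx27KD and Ddx54KD, 2 glycolysis genes rose and 2 to 6 of 27 fell (fry 0.242 to 0.855), and 2 or 3 rose and 7 to 11 fell with the block. For 2-cell-like genes, 1 rose and 1 fell in Ddx10KD (fry 0.642), and 6 rose and 1 fell in Ddx27KD (0.0588; 1 and 1 over the list alone, 10 and 1 with the block). Summed levels of that list were 119 ± 16.5 and 157 ± 29.4 CPM there, against 158 ± 13.0 in EGFPKD (SD, n = 3). At most 2 of 12 snoRNA host transcripts (6 with the block; fry 0.304 to 0.666) and 1 of 20 histone genes (fry 0.775 to 0.986) were called in a knockdown. The signs of the median or mean and of fry differed for endoderm (Ddx10KD, Ddx24KD), ectoderm (Ddx10KD, Ddx54KD), trophoblast (Ddx10KD, Ddx24KD, Ddx27KD), stress of the endoplasmic reticulum (Ddx10KD, Ddx54KD), interferon (Ddx27KD) and histones (Ddx54KD). These 11 lists, and the 3 on R-loops, RNA polymerase I and DEAD-box genes, had adjusted p = 0.720 or more with an estimated correlation in the 4 knockdowns, apart from 2-cell-like genes in Ddx24KD and Ddx54KD, given above.

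Fibroblast markers, listed as another cell type that a culture could hold, rose in 2 of 13 cases and fell in 1 in each knockdown (2 to 6 and 1 or 2 with the block). The actin-binding gene Cald1 was higher by 1.28 to 1.48 (log2) and Twist1 by 0.83 to 0.92, and Thy1 was lower, at -0.76 to -0.48. In Ddx54KD the Twist1 call was lost without Ddx54KD replicate 2 (adjusted p 0.0592), and the Thy1 call without EGFPKD replicate 1 (0.158) or Ddx54KD replicate 2 (0.0672) or 3 (0.112). The list had fry adjusted p of 0.00193 to 0.0162 toward higher levels and adjusted p = 0.722 to 0.826 with an estimated correlation. The 13 protein-coding genes of the mitochondrial genome were not in the files. Among the other 9 splits of each knockdown's 6 libraries, camera with its preset correlation called up to 11 lists, as many as in the real comparisons (7 to 10). Each side of those other splits holds knockdown and EGFPKD libraries unequally, so part of the knockdown difference remains in them. Their counts therefore cannot give a rate of false calls for camera. By a choice made after these counts were seen, the list results here rest on fry and on the counts of called members. Neither compares a list with other genes, and the counts are to be read beside the shares of all genes called, given above.

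The 4 knockdowns were compared to see which changes they shared. Beyond the p53 and ATF4 genes above, Casp14, a caspase of keratinising cells, rose 10.1-fold in Ddx10KD (95% counting interval 5.57 to 20.03), 13.1-fold in Ddx24KD (7.29 to 25.9), 14.6-fold in Ddx27KD (8.14 to 28.8) and 12.9-fold in Ddx54KD (7.19 to 25.5). The phospholipase Plcd4 rose by 3.11 to 3.44 (log2). Early B-cell factor 2 (Ebf2) had 3 counts over the 3 control libraries and 44 to 124 over each knockdown's 3, a ratio of 14.5 (95% counting interval 4.64 to 72.9) in Ddx54KD and 41.3 (13.8 to 203) in Ddx27KD. Klhl30 and D730001G18Rik had 1 control count and 20 to 38 in each knockdown, with ratios of 19.7 (95% counting interval 3.14 to 815) to 30.99 (5.16 to 1263) for Klhl30 and 20.2 (3.23 to 836) to 38.0 (6.42 to 1539) for D730001G18Rik. Htr4, Arpp21 and Cbln2, with 1 or 2 control counts, and Cpz and Ano3, given above, were the others of the 10 genes whose smallest change over the 4 knockdowns was largest.

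In total 2384 genes were called in the same direction in all 4 knockdowns, 1336 higher and 1048 lower. If the 4 lists of calls were independent, 8.05 and 4.88 would be shared. With the replicate block the counts were 3722, 1936 and 1786. More genes were higher than lower by edgeR in each knockdown and among the shared genes. At a probability of at least 0.95, the authors' deposited tables had more lower than higher in Ddx10KD, Ddx27KD and Ddx54KD. The balance by edgeR also depended on the scaling of the libraries. With the block and a length and GC correction that also removed each library's mean, 2555 were higher and 4133 lower in Ddx10KD, 2391 and 3989 in Ddx24KD, 2526 and 4594 in Ddx27KD, 2172 and 4040 in Ddx54KD, and 1434 and 2740 alike in all 4. Of 6286 genes called in any knockdown, 1737 were called in 1 only and 2 were called in opposite directions. Across genes, which are not independent replicates, log2 changes of the 6 pairs of knockdowns had Pearson correlations from 0.857 (Ddx10KD and Ddx54KD) to 0.919 (Ddx24KD and Ddx27KD). All 4 comparisons used the same 3 control libraries, too few to divide. Groups without change were simulated against controls that were redrawn from the EGFPKD means. They gave correlations of 0.494 to 0.498. In each of 20 simulations edgeR called 0 genes alike in all 4, and a comparison had 0.0375 calls on average. The measured covariances were 0.196 to 0.241 against 0.0182 to 0.0186 in the simulations, an excess of 0.178 to 0.223, and part of the excess may come from the shared controls.

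A test over all 5 groups, which asked whether a gene differed between any of them, called 4151 genes by edgeR, and 7098 with the replicate block. Levels of the p53 target Plk2 ran from 21.6 CPM in EGFPKD to 160.3 in Ddx27KD.

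Direct comparisons between knockdowns asked where they differed. Ddx10KD had lower levels of 2-cell-like genes than Ddx24KD: 9 of 24 were called lower (19 adjusted over the list alone, 17 with the block), with a median log2 difference of -0.94. Zscan4f differed by -1.25 ± 0.17 (SE), Zscan4c by -1.10 ± 0.17, AF067061 by -1.10 ± 0.18 and Gm8300 by -0.97 ± 0.15. The fit of these 2 groups alone lost the calls for Zscan4c (adjusted p 0.0861) and Gm8300 (0.0573), and leaving out Ddx10KD replicate 3 lost those for AF067061 (0.0606) and Gm8300 (0.0544). The list had fry adjusted p 0.00335 and adjusted p = 0.0146 with an estimated correlation, or 0.0623 with the block. Ribosomal protein genes were lower in Ddx10KD by a median of -0.12, with 2 of 79 called (23 over the list alone, 40 with the block), fry adjusted p 0.149 (0.00436 with the block) and adjusted p = 0.430 with an estimated correlation (0.101 with the block). Mitotic genes differed by a median of -0.14, with 1 of 25 called (14 over the list alone, 14 with the block), fry adjusted p 0.00384 and adjusted p = 0.0718 with an estimated correlation. Tmem181a was higher in Ddx10KD (0.86 ± 0.14). By edgeR 59 genes differed, 15 higher and 44 lower in Ddx10KD, and 776 did with the replicate block, 173 by DESeq2 and 18 in a fit of the 2 groups alone. Without Ddx10KD replicate 2 or 3 the count was 34 or 28.

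Against Ddx27KD, Ddx10KD had more Ibtk (0.50 ± 0.07, log2, SE) and less of the respiratory chain assembly gene Cox7a2l (-0.66 ± 0.07). The long noncoding RNA Neat1 was lower, at -0.92 (adjusted p 0.0120), a call lost without Ddx10KD replicate 2 (0.0880) or Ddx27KD replicate 1 (0.0817) or 2 (0.0596). Mitotic genes were lower by a median of -0.11 (0 of 25 called by edgeR, 8 lower over the list alone, 8 with the block; fry adjusted p 0.0382, and adjusted p = 0.322 with an estimated correlation). Of 32 genes called by edgeR, 9 were higher and 23 lower in Ddx10KD, and the count was 766 with the block, 174 by DESeq2 and 13 in the fit of the 2 groups alone. It was 21, 8 and 16 without Ddx10KD replicate 1, 2 and 3, and 14 and 9 without Ddx27KD replicate 1 and 2. Ribosomal protein genes, not called by fry in this comparison (0.389), were called with the block (0.0261, with 27 of 79 lower), and had adjusted p = 0.806 with an estimated correlation, or 0.425 with the block. Against Ddx54KD, the same knockdown had more of the stress ligand Raet1c (1.10 ± 0.18) and less Neat1 (51.4 ± 5.37 to 25.6 ± 4.49 CPM, from Ddx54KD to Ddx10KD). Genes of the 2-cell-like state were lower by a median of -0.70, with 6 of 24 called (15 over the list alone, 10 with the block), fry adjusted p 0.0488 and adjusted p = 0.307 with an estimated correlation. Zscan4f differed by -0.96 (adjusted p 0.0116), a call lost without Ddx10KD replicate 2 (0.0639) or 3 (0.0694). By edgeR 205 genes differed, 99 higher and 106 lower in Ddx10KD, with 1517 under the block, 439 by DESeq2 and 120 in the fit of the 2 groups alone. It was 96, 63 and 44 without Ddx10KD replicate 1, 2 and 3, and 95, 51 and 80 without Ddx54KD replicate 1, 2 and 3. By fry, 5 further lists were called in this comparison with the block alone: ribosomal proteins (0.0149, from 0.276; 30 lower), mitosis (0.00643, from 0.137), ectoderm (0.00515, from 0.198), endoplasmic reticulum stress (0.0278, from 0.198) and pluripotency (0.0278, from 0.261). With an estimated correlation and the block these had adjusted p = 0.378, 0.378, 0.118, 0.527 and 0.462, and 0.617 to 0.778 without the block.

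Fewer genes differed among Ddx24KD, Ddx27KD and Ddx54KD. Between Ddx24KD and Ddx27KD, edgeR called both targets and Raver1-fdx1l (1.05 ± 0.16, log2, SE, higher in Ddx24KD; adjusted p 0.0289), 3 genes, with 8 under the block and 5 by DESeq2. The Raver1-fdx1l call was lost in the fit of the 2 groups alone (adjusted p 0.183) and without Ddx24KD replicate 2 (0.202) or 3 (0.114) or Ddx27KD replicate 1 (0.354) or 3 (0.351). Between Ddx27KD and Ddx54KD the 2 called genes were the 2 targets, with 375 under the block, 28 by DESeq2 and 14 in the fit of the 2 groups alone. Between Ddx24KD and Ddx54KD, 8 genes differed, 5 higher and 3 lower in Ddx24KD, and 250 did with the block, 20 by DESeq2, 5 under a stricter count filter and 2 in the fit of the 2 groups alone. Among the 8, the syntaxin Stx3 was higher in Ddx24KD (0.42 ± 0.05, adjusted p 0.00159, but 0.198 in the fit of the 2 groups alone). The count was 4, 26 and 3 without Ddx24KD replicate 1, 2 and 3, and 4, 3 and 3 without Ddx54KD replicate 1, 2 and 3. The ectoderm markers were higher in Ddx24KD than in Ddx54KD by a median of 0.22 (0 of 14 called by edgeR, 5 over the list alone, 4 with the block), with adjusted p = 0.0303 with an estimated correlation and fry adjusted p 0.0573 (0.000333 with the block). Within that list Otx2 differed by 0.78 ± 0.17 (adjusted p 0.247) and Pou3f1 by 1.04 ± 0.23 (0.247), both called with the block. With the block alone, fry also called mitosis between Ddx24KD and Ddx54KD (0.0294, from 0.511), and mesoderm (0.0159, from 0.191) and ectoderm (0.0104, from 0.366) between Ddx27KD and Ddx54KD. With an estimated correlation and the block the 3 had adjusted p = 0.439, 0.0810 and 0.0711, and 0.815, 0.361 and 0.361 without the block.

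**Figure D3:**
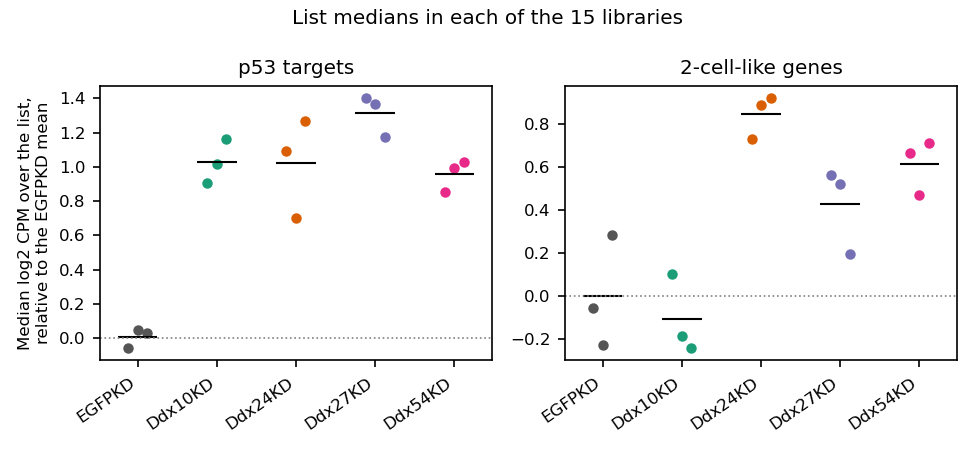
Median log2 CPM of p53 targets and of 2-cell-like genes in each of the 15 libraries, relative to the EGFPKD mean of each gene. Dots are libraries, grouped by knockdown. For p53 targets all 12 knockdown libraries lay above the 3 EGFPKD libraries, and for 2-cell-like genes the 3 Ddx24KD libraries lay above the 3 Ddx10KD libraries.

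The authors' deposited tables give each gene's posterior probability of differential expression by EBSeq. At a probability of at least 0.95 the authors' deposited tables list 3194 genes for Ddx10KD (1584 higher, 1610 lower), 2316 for Ddx24KD (1200, 1116), 3433 for Ddx27KD (1654, 1779) and 2445 for Ddx54KD (1200, 1245). Of the genes listed in the authors' deposited tables, 92.9%, 92.7%, 94.5% and 91.7% were also called by edgeR in the same direction, and no gene called by both went in opposite directions. In the other direction, 1472 of 4438, 1879 of 4026, 1545 of 4788 and 1240 of 3483 edgeR calls fell short of that probability. Among them were genes given above as changed alike in all 4 by edgeR, such as Klhl30 (1.11e-09) and D730001G18Rik (6.31e-09) in Ddx10KD. Casp14, Plcd4 and Ebf2 passed 0.95 in all 4 of the authors' deposited tables. In the authors' deposited tables, a total of 676 genes were higher and 577 lower in all 4 knockdowns. Across genes, the log2 ratios of the authors' deposited tables and the edgeR log2 changes had Pearson correlations of 0.999 for Ddx10KD, Ddx27KD and Ddx54KD, and 0.967 for Ddx24KD. In the authors' deposited table for Ddx24KD the ratios did not follow from the 6 libraries of that comparison, so that table's values could not be recomputed.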

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

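Among the tests below, those of the shared response against chance values of the control libraries, gene length and GC content, and an EGFPKD offset, and that of the p53 response behind the 2-cell-like difference, were chosen only after the result was seen.

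A difference between groups, by a test of the difference itself, drew attention to 5 list results. Ddx10KD was lower than Ddx24KD in 2-cell-like genes (median log2 difference -0.94, adjusted p 0.00335 by fry), in mitotic genes (-0.14, 0.00384) and in genes of endoplasmic reticulum stress (-0.078, 0.0456). It was lower than Ddx27KD in mitotic genes (-0.11, 0.0382), and lower than Ddx54KD in 2-cell-like genes (-0.70, 0.0488). Against other genes, with an estimated correlation, the first had adjusted p = 0.0146, a call lost with the replicate block (0.0623). The others, in that order, had adjusted p = 0.0718, 0.226, 0.322 and 0.307 with an estimated correlation.

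The 2-cell-like difference between Ddx10KD and Ddx24KD was weighed first. Reads divided in another way between the near-identical Zscan4 copies would leave their sum equal, but the summed level was 2.34-fold higher in Ddx24KD (96.3 ± 19.4 against 41.2 ± 9.27 CPM, SD, n = 3; whole list 197 ± 28.8 against 119 ± 16.5). The library Ddx24KD replicate 2 alone was not the source either, since the median without it was -0.97. A weaker p53 response in Ddx10KD would put p53 targets lower there too, and their median difference was 0.0245. Depletion of Ddx24, against that of Ddx10, may be the cause and stays open, and off-target effects of the small interfering RNA were not tested.

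The shared response of the 4 knockdowns was weighed second. In each of 20 simulations of unchanged groups, edgeR called 0 genes alike in all 4, where 2384 were measured. Controls and groups alike were redrawn from the EGFPKD means with the fitted dispersions, each gene by itself. The simulations therefore cover independent chance spread of single genes. They cannot exclude a chance shift of the real EGFPKD libraries that many genes share, since such a shift is part of the means used. With the replicate block and the correction for gene length and GC content, 97.0% of the 2384 genes kept call and direction (93.2% in a first version of the correction, which also removed each library's mean and was revised after its result was seen), which argues against these 2 biases as the whole cause. An offset of the EGFPKD libraries as the whole cause cannot be told apart from depletion of the helicases, since EGFPKD is the single control group. Ddx27KD and Ddx54KD, which such an offset would move equally along the axis from EGFPKD to the other 2 knockdowns, differed by 19.3% of that distance (95% interval -17.8 to 56.3).

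The last pattern weighed was the ribosomal protein genes, lower in Ddx10KD than in Ddx24KD by a median of -0.12 (log2; fry adjusted p 0.149, or 0.00436 with the replicate block; 0.430 with an estimated correlation, or 0.101 with the block; 2 of 79 called). With the block and the correction for gene length and GC content the median was -0.11, which argues against those biases as the whole cause. A lower level of all messages with a 5-prime terminal oligopyrimidine tract is a candidate explanation. It predicted lower levels of 14 further messages of this class, and their median was -0.11 (fry p 0.00716). The test was prompted by translation factors already seen to be lower in this same comparison, which were left out of it. The same libraries were used, so its result is not independent of the first. Both lists are tested against no other genes by fry, and why the class would differ between these 2 knockdowns was not tested.

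Other splits of the same libraries were counted. For genes, the 10 splits of 6 libraries are too few for a share under 0.05. The real splits against EGFPKD called 4438 genes (Ddx10KD), 4026 (Ddx24KD), 4788 (Ddx27KD) and 3483 (Ddx54KD), and the highest of the other splits 0. Between knockdowns the real splits called 59, 32, 205, 3, 8 and 2 genes (Ddx10KD against Ddx24KD, Ddx27KD and Ddx54KD, then Ddx24KD against Ddx27KD and Ddx54KD, then Ddx27KD against Ddx54KD), and the highest of the others 0, all by edgeR. In each of these 10 comparisons 1 split, the real one, gave as many. Of the 10 splits 4 part all 3 pairs of equal replicate numbers, as the real one does, and the others part 1 pair; the highest count apart from the real one was 0 in both kinds. For lists by camera with its preset correlation, the 10 splits are again too few. The real values were 8, 10, 7 and 9 lists, the highest of the others 10, 11, 9 and 10, and 4, 3, 7 and 5 of the 10 splits gave as many. Among the other splits that part all 3 pairs, the highest were 8, 10, 8 and 8. By fry the real splits called 10 lists each and the others 0. In the other splits each side mixes libraries of the compared groups. A difference between the groups then widens the spread within each side and shrinks the contrast. Counts of 0 by edgeR or fry were therefore likely beforehand, and give no rate of false calls. For camera, part of the difference remains in these splits, so its counts give no such rate either.

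The 15 libraries were also split into 5 groups of 3 in 100 ways, drawn without regard to the pairing by replicate number. The test over all 5 groups called 4151 genes. The highest other count was 4122, in a split that also kept the 3 EGFPKD libraries together. For genes called alike in all 4 knockdowns the count was 2384 and the highest of the others 1. In both, 1 of the 100 splits, the real one, gave as large a value, which argues against a chance division of all 15 libraries. The shared count also depends on which group is the control, and the split with EGFPKD together gave 0 such genes. These splits therefore bear on the parting of EGFPKD from the rest, and not on how the knockdown libraries divide into 4 groups. With 1 or 2 of the 100 splits as large, the same limits hold for the 6 correlations of log2 changes. These were 0.882 (Ddx10KD and Ddx24KD; highest other 0.884, and 2 of 100 splits as large), 0.899 (Ddx10KD and Ddx27KD; 0.875), 0.857 (Ddx10KD and Ddx54KD; 0.808), 0.919 (Ddx24KD and Ddx27KD; 0.846), 0.891 (Ddx24KD and Ddx54KD; 0.812) and 0.912 (Ddx27KD and Ddx54KD; 0.850), the last 5 with 1 split as large.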

How the results depend on the processing

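The block with the length and GC correction, in both versions, and the fit without the replicate 2 libraries, were chosen only after the results were seen. No called named gene, target or list changed sign under the alternatives fixed beforehand. This count of signs covers neither the other called genes nor the alternatives chosen after the results were seen. Signs of uncalled values turned in 19 cases for named genes and 29 for lists, 3 of them by fry (endoderm in Ddx10KD and Ddx54KD, histones in Ddx54KD), all at adjusted p of 0.510 or more. The 4 targets kept their calls under all 8 alternatives and each library left out: log2 changes ran from -2.61 to -2.28 (Ddx10), -1.79 to -1.58 (Ddx24), -2.16 to -2.11 (Ddx27) and -1.94 to -1.71 (Ddx54).

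A 2-fold minimum, which by construction removes small changes, left 713 genes in Ddx10KD against EGFPKD, 646 in Ddx24KD, 796 in Ddx27KD and 534 in Ddx54KD, and 378 alike in all 4. Between knockdowns it left 20 genes for Ddx10KD against Ddx24KD, 3 against Ddx27KD and 12 against Ddx54KD, and 4 for Ddx24KD against Ddx54KD. In the authors' deposited tables it left 468, 395, 536 and 354 of 3194, 2316, 3433 and 2445 calls (Ddx10KD, Ddx24KD, Ddx27KD, Ddx54KD). A posterior probability of 0.99 left 2806, 1910, 3063 and 2046 calls in the authors' deposited tables. An adjusted p under 0.01, again stricter by construction, left 2673, 2310, 3039 and 1860 genes in the 4 knockdowns, 28, 13 and 43 for Ddx10KD against Ddx24KD, Ddx27KD and Ddx54KD, 3 for Ddx24KD against Ddx54KD, 2336 over the 5 groups and 1320 alike in all 4.

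With the replicate block 6310 genes were called in Ddx10KD, 5907 in Ddx24KD, 6571 in Ddx27KD and 5570 in Ddx54KD. The block gave 7098 over the 5 groups and 3722 alike in all 4 knockdowns. Between knockdowns it called 776 (Ddx10KD and Ddx24KD), 766 (Ddx10KD and Ddx27KD), 1517 (Ddx10KD and Ddx54KD), 8 (Ddx24KD and Ddx27KD), 250 (Ddx24KD and Ddx54KD) and 375 (Ddx27KD and Ddx54KD). With the length and GC correction added, 5741 were called in Ddx54KD and 3774 alike in all 4. The first version of that correction, which also removed each library's mean, gave 6688 in Ddx10KD, 6380 in Ddx24KD, 6212 in Ddx54KD and 4174 alike in all 4. By construction it rescales the libraries, which moved the median log2 change of all genes by -0.07 to -0.06. The balance of calls turned: 2555 higher and 4133 lower in Ddx10KD, 2391 and 3989 in Ddx24KD, 2526 and 4594 in Ddx27KD, 2172 and 4040 in Ddx54KD, and 1434 and 2740 alike in all 4. With the correction of the trend alone, Ddx27KD had 3307 higher and 3327 lower. The other alternatives run on the expected counts kept more genes higher than lower in each knockdown. The authors' deposited tables, at a probability of 0.99, had 1393 higher and 1413 lower in Ddx10KD and 1014 and 896 in Ddx24KD. In Ddx27KD they had 1483 and 1580, and in Ddx54KD 1023 and 1023. DESeq2 called 173, 174, 439, 5, 20 and 28 genes in the same 6 pairs. A fit of the compared groups alone, with fewer samples, called 18, 13 and 120 for Ddx10KD against Ddx24KD, Ddx27KD and Ddx54KD, 2 for Ddx24KD against Ddx54KD, and 14 for Ddx27KD against Ddx54KD. The filter of 10 CPM left 5 for Ddx24KD against Ddx54KD. Apart from the thresholds and the fewer samples, the cause was not tested.

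Leaving out 1 library at a time, which leaves fewer samples, gave 2232 to 3469 genes in Ddx54KD, 28 to 60 for Ddx10KD against Ddx24KD, 8 to 30 against Ddx27KD and 44 to 96 against Ddx54KD. For Ddx24KD against Ddx54KD it gave 3 to 26, the highest without Ddx24KD replicate 2. Ranges within 1.5 times of the full count were 3193 to 3974 (Ddx10KD), 2866 to 4307 (Ddx24KD), 3880 to 4201 (Ddx27KD), 2808 to 4602 (5 groups), 1751 to 2628 (alike in all 4), 2 to 3 (Ddx24KD against Ddx27KD) and 2 to 2 (Ddx27KD against Ddx54KD). Without all replicate 2 libraries the counts were 2161 in Ddx54KD and 1589 alike in all 4. The other counts of genes stayed within 1.5 times, including all 12 with RLE factors, upper-quartile factors, limma-voom and no filter.

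Correlations of log2 changes fell without a count filter to 0.644 (Ddx10KD and Ddx24KD), 0.665 (Ddx10KD and Ddx27KD), 0.637 (Ddx10KD and Ddx54KD), 0.656 (Ddx24KD and Ddx27KD), 0.647 (Ddx24KD and Ddx54KD) and 0.658 (Ddx27KD and Ddx54KD). Over genes called in either comparison they were 0.942 (Ddx10KD and Ddx27KD), 0.919 (Ddx10KD and Ddx54KD) and 0.951 (Ddx24KD and Ddx54KD). Spearman correlations were 0.847 (Ddx10KD and Ddx27KD) and 0.789 (Ddx10KD and Ddx54KD), and the filter of 10 CPM gave 0.947 (Ddx24KD and Ddx54KD). Leaving out libraries gave 0.858 to 0.921 for Ddx24KD and Ddx27KD, and other correlations moved by less than their spread. The cause was not tested.

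Lists called by camera went from 8, 10, 7 and 9 with its preset correlation to 1 in each knockdown with an estimated correlation, and 30 list calls were lost in all. The preset allows a correlation of 0.01 for every list. In Ddx27KD 11 lists were called without a filter (the cause was not tested). Beyond these, fry added 10 calls and lost 4, limma-voom added 4 and lost 4 (mesoderm in all 4 knockdowns), and libraries left out in turn added 12 and lost 9. For named genes, libraries left out in turn kept 3400 results on their side of the threshold, lost 281 calls and added 15. The block added 66 calls and lost none, DESeq2 added 27 and lost none, and fits of the compared groups alone added 8 and lost 24.

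Depth limits the genes with few counts: Casp14, Ebf2, Klhl30, Htr4, Arpp21, Cbln2 and D730001G18Rik had too few control counts for a narrow ratio. At this depth and replication, 74% of simulated 1.5-fold changes were recovered, so changes of that size or smaller may have been partly missed. The simulation changed 50 genes at each size. The real comparisons called far more genes, which makes the threshold on p less strict, so the share need not hold for them.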

Other observations

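The 4 translation factors named first here were chosen only after their values were seen. By edgeR, Eef1b2 (-0.35), Eef2 (-0.26), Eif4b (-0.47) and Eif3f (-0.32) were called lower in Ddx10KD than in Ddx24KD (log2). They prompted the test of further messages with a 5-prime terminal oligopyrimidine tract and were left out of it for that reason. Of the 14 messages in that test, Eef1a1 was the single one called.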
